A study of Mus musculus with 6 samples.

How the data were processed

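RNA was sequenced from cells isolated as primary lung endothelial cells, from mice with a floxed Fundc1 gene (FL, 3 libraries) and from mice with an endothelial knockout of that gene (EC-KO, 3 libraries). Per the labels' protocols, cells were isolated from lungs with magnetic beads, dead cells were removed, cells were kept in endothelial medium with serum, and libraries were made from polyA RNA. The labels do not name the antibody on the beads or the time in culture, and sample titles use the abbreviation PAECs while the protocols describe isolation from lungs.

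The deposited table holds raw counts per Ensembl gene, 1 column per library, in the layout that featureCounts writes, per the file headers. The submitters' processing notes name STAR 2.7.10b, featureCounts 2.0.3 and the mm10 build, without order or role. Alignment settings, annotation release and strand setting are not given in the sources used here. A summary of alignments per class, also deposited as counts, gave the shares that the authors' counting assigned to genes, which were 75.5%, 76.3% and 77.8% of alignments in FL 1, 2 and 3 and 74.0%, 74.7% and 72.4% in EC-KO 1, 2 and 3, so the groups did not overlap. Alignments without a feature were 14.4% in EC-KO 3 and 9.10% to 10.8% in the other libraries. Alignments to several places made up 9.10% to 11.5% and were set aside, as were 3.60% to 3.98% that were ambiguous between genes. Counts of near-identical copies, such as Hspa1a and Hspa1b or the globin genes, and of genes that overlap others are therefore uncertain. The same holds for the low counts of Tagln, Gpx1, S100a4, mt-Co2, mt-Co3 and mt-Atp6. The count table had 2 further per-sample columns that match no sample in the labels, and these were not used.

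The table lists 56941 genes, of which 51948 shared their identifier with the GENCODE annotation of GRCm38 (mm10) at hand and took their symbol from it. Only 2.80% of these had the same start in both, and 1441 had the same start and end. The coordinates in the table are therefore of another build than the one the notes name, and coordinates are printed as the table gives them, with the build unresolved.

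Counts were analysed as deposited with edgeR 4.0.16 in R 4.3.3. Genes with few counts were removed with filterByExpr, which left 18562 of 33412 genes with any count, and library sizes were scaled with TMM factors. The test was the robust quasi-likelihood F test (glmQLFit, glmQLFTest) of EC-KO against FL over all 6 libraries without covariates, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are log2 values of EC-KO over FL with their standard errors. Each standard error was taken as the absolute log2 fold change divided by the square root of the F statistic. It is therefore no measure of precision separate from the p-value. Levels are CPM, counts divided by library size with TMM scaling. Depth was between 26.7 M and 34.3 M counts per library, and the common biological coefficient of variation was 25.5%.

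A total of 25 lists of genes by program and 10 lists of marker genes by cell type or sex were tested with camera on voom values (limma 3.58.1) with a preset correlation of 0.01. Adjustment was made separately within the program lists and within the marker lists. Each list was also tested with an estimated correlation and with fry. The program lists were mitophagy and autophagy, mitochondrial fission, fusion and biogenesis, ER-mitochondria contact, nuclear-encoded respiratory chain, mitochondrially encoded proteins, glycolysis, hypoxia, antioxidant response, integrated stress response, chaperones, pan-endothelial identity, aerocytes, general capillary, arterial and venous endothelium, BMP signalling, mesenchymal and matrix genes, secreted mediators, NF-kB inflammation, interferon response, proliferation, p53 response, fatty acid use, cholesterol synthesis, and immediate early and heat shock genes. The marker lists were smooth muscle and pericyte, fibroblast, mesothelial, epithelial, macrophage, neutrophil and mast cell, lymphocyte, lymphatic, erythroid and platelet, and sex-linked genes. A further 5 lists were written after the data had been seen: other targets of the aryl hydrocarbon receptor, keratin-rich transitional epithelium, adventitial fibroblast, cytosolic heat shock and immediate early genes.

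The tests, the lists, the rule for named genes and the first set of alternatives were chosen before the data were examined. The rule named Fundc1 and, among called genes with an average log CPM of at least 1 whose groups did not overlap, the 10 with the largest rise and the 10 with the largest fall, without predicted loci and sex-linked genes. It also named up to 2 called members per direction of each list by smallest p, the most abundant member of a list with none called, and 10 genes of hypoxia signalling, vasoactive signalling and mitophagy whatever their result. In all 126 genes were named by it. Other list members and single genes given in the text were chosen after their values were seen.

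Alternatives were RLE, upper-quartile and library-size scaling, no filter and a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a fit that was not robust, the replicate number as a block, leaving out each library in turn, library sizes without mitochondrially encoded genes, other thresholds, and a test against a change of 1.5 times (glmTreat). A comparison of 2 against 2 libraries (FL 1 and EC-KO 2 left out) and a scaling to the pan-endothelial list were added after the data had been seen. Relative to FL, FL 1 had the lowest pan-endothelial mean of the FL libraries (-0.20) and EC-KO 2 the highest of the EC-KO libraries (-0.52). Leaving both out therefore widened the difference in those markers by choice.

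The gene test was tested on simulated data: 10 sets of counts drawn from the means and library sizes of the real comparison, each with 200 genes changed. With dispersions drawn from the trend, the test recovered 4.63% of genes changed 1.5-fold, 39.0% of those changed 2-fold and 88.4% of those changed 4-fold, and 4.88% of calls were false. With gene-wise dispersions it recovered 3.55%, 24.8% and 78.0%, and 10.3% of calls were false, above the share that the threshold aims at. These runs tested about 18069 and 18058 genes per set. The real comparison called 5029 genes, far more than the 200 changed in each set, which alters the p-value that the adjustment requires. Recovery and the share of false calls in the real comparison may therefore differ from these figures. A simulated list with raised genes gave a camera p of 5.00e-57 and an unchanged list gave 0.216. Genes were simulated independently of each other, so these values do not show how camera behaves on lists whose members vary together. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.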

Results

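Gene expression was measured in cells isolated from mouse lungs as endothelial cells and kept in medium. There were 3 libraries with a floxed Fundc1 gene (FL) and 3 libraries with an endothelial knockout of that gene (EC-KO). Markers of other lung cells were also detected, so values describe the whole isolate. Fundc1 encodes a receptor for mitophagy in the outer mitochondrial membrane, and the series was deposited under the theme of pulmonary hypertension. Total gene counts were 26.7 M, 34.0 M and 34.3 M in FL 1, 2 and 3 and 32.9 M, 33.5 M and 29.7 M in EC-KO 1, 2 and 3. Across genes, which are not independent replicates, log CPM values of libraries correlated at 0.963 to 0.984 within a group and at 0.928 to 0.950 between groups. The first principal component held 59.7% of the variance and separated the groups, and the second held 16.8% and set EC-KO 2 (-62.8) apart from EC-KO 1 (18.0) and EC-KO 3 (39.0). Nothing in the labels states that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

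Fundc1 transcripts were lower in the knockout libraries but remained detectable in each. Levels were 25.0, 31.9 and 30.7 CPM in FL 1, 2 and 3 and 14.1, 18.1 and 12.8 CPM in EC-KO 1, 2 and 3. The means were 29.2 ± 3.67 and 15.0 ± 2.78 CPM (SD, n = 3 each), a log2 fold change of -0.96 ± 0.19 (SE) with an adjusted p of 0.00796 in edgeR's quasi-likelihood test. The gene (ENSMUSG00000025040) lies on chromosome X, 17422803 to 17438564, minus strand, in the coordinates of the count table, whose build is not resolved. A gene count includes exons outside the deleted part, so remaining reads need not come from an intact transcript. They may also come from other cells in the isolates. Endothelial markers were lower in the same libraries by about as much (list median -1.05), and scaled to that list, an alternative chosen after seeing the data that moved the median gene by 1.12, Fundc1 was at 0.12 ± 0.31 (adjusted p = 0.736).

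The knockout libraries differed from the floxed ones in 5029 of 18562 tested genes (27.1%), of which 2515 were higher and 2514 lower. Among called genes of sufficient level whose groups did not overlap, the largest falls were those of Cyp1b1 (log2 fold change -7.10), Ahrr (-6.66) and Cyp1a1 (-5.18), which are known targets of the aryl hydrocarbon receptor. Cyp1a1 went from 2115 ± 853 to 58.3 ± 18.4 CPM and Cyp1b1 from 1122 ± 337 to 8.20 ± 7.30 CPM (SD, n = 3 each), with adjusted p-values of 0.000352 and 0.000451 in edgeR. Next came the myeloid genes Nlrp12 (-4.82), Mmp12 (-4.46), Cxcr2 (-4.02), Tlr8 (-4.00) and Mgl2 (-3.95), the laminin gene Lama1 (-4.19) and the locus AC132455.2 (-3.98). Among the largest rises were genes of epithelial barriers and keratinising cells, Sprr1a (5.14), Cldn4 (4.58) and Ivl (4.41). The others of that group were the cytokine Il11 (4.90), the matrix protease Mmp3 (4.60), the bradykinin receptor Bdkrb1 (4.36), the growth factor Gdnf (4.27), the scavenger receptor Scara5 (4.20), the amino acid transporter Slc6a14 (4.20) and Nipal1 (4.50).

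A change of at least 2-fold was seen in 3100 called genes (1741 higher, 1359 lower), and 243 changed at least 8-fold (181 higher, 62 lower). At an unadjusted p under 0.05 there were 7540 genes, and the groups did not overlap in 8423 genes (45.4%), where chance gives 10%. The number of changed genes was 2626 without FL 2, 2547 without FL 3, 2832 without EC-KO 1 and, as an alternative chosen after seeing the data, 7554 without FL 1 and EC-KO 2. That alternative left out the libraries nearest the other group in pan-endothelial markers (-0.20 in FL 1, -0.52 in EC-KO 2), which widened that difference by choice.

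**Figure D1:**
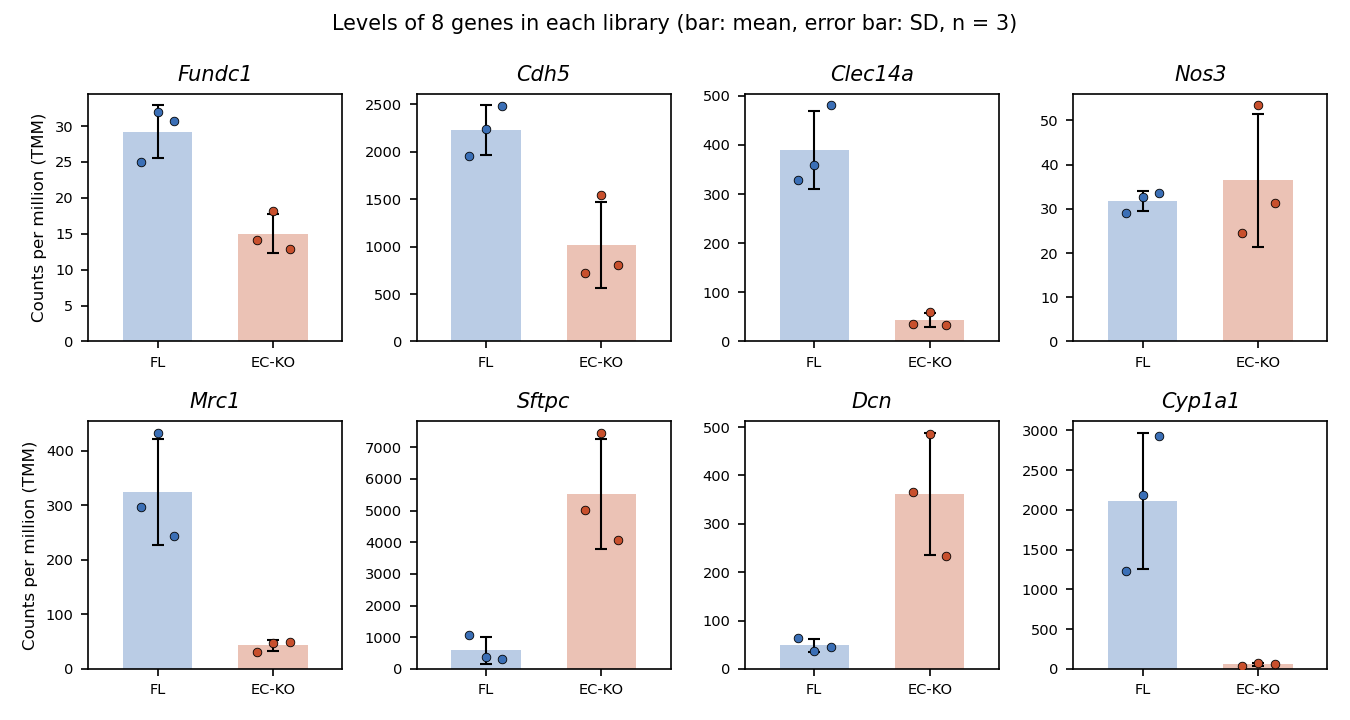
Levels of 8 genes in CPM (vertical axes, linear, from 0) in the 3 FL and 3 EC-KO libraries, with bars for the group mean, error bars for the SD and points for single libraries. Fundc1 was at 25.0 to 31.9 CPM in FL and 12.8 to 18.1 CPM in EC-KO, and Cyp1a1, Mrc1 and Clec14a were lower while Sftpc and Dcn were higher in EC-KO.

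Among genes that define endothelial cells, falls outnumbered rises in the knockout libraries. In the pan-endothelial list, 20 of 37 members fell and 0 rose (25 lower when adjusted over the list alone), with a median log2 fold change of -1.05. Cdh5, the endothelial cadherin, fell by 1.13 on the log2 scale, Pecam1 by 1.14, the transcription factor Sox17 by 1.71 and the surface lectin Clec14a by 3.17. Clec14a went from 390 ± 80.2 to 43.2 ± 14.3 CPM (edgeR, adjusted p = 0.000436). The list as a group lay below other genes (camera, adjusted p = 2.25e-10), but not with an estimated correlation (adjusted p = 0.684 with an estimated correlation). Mean values of the list relative to FL were -1.37, -0.52 and -1.39 in EC-KO 1, 2 and 3. Without FL 2, FL 3, EC-KO 1 or EC-KO 3, Cdh5 (adjusted p = 0.0664, 0.0778, 0.0814 and 0.0726) and Pecam1 (0.0660, 0.0917, 0.0953 and 0.0756) were not called. The number of members that fell was 12 without FL 2, 11 without FL 3, 11 without EC-KO 1, 12 without EC-KO 3 and 32 without EC-KO 2.

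Lists of vessel subtypes were tested 1 by 1, and not against each other. Some members are on several lists, so falls in different lists are not all separate. Plvap, Ptprb and Tek are on the general capillary and pan-endothelial lists. Sox17 is on the arterial and pan-endothelial lists, and Cxcl12 on the general capillary and arterial lists. Of 12 markers of general capillary cells 8 fell and 0 rose (9 lower when adjusted over the list alone, median -1.75), among them the chemokine Cxcl12 (-2.24) and the incretin receptor Glp1r (-1.96). In the arterial list 14 of 26 fell and 2 rose (15 and 2 when adjusted over the list alone, median -0.86), with Hey1 at -1.68 and Sox17 at -1.71 against Mgp at 1.72 and Alpl at 2.41, where Mgp was not called without the filter for low counts (0.0598). Mgp and Alpl rose least without EC-KO 2 (1.13 and 1.90) and most without EC-KO 3 (2.04 and 2.68). Beside them, fibroblast marker means relative to FL were 1.59, 2.30 and 0.79 in EC-KO 1, 2 and 3. Of the 16 venous genes 8 fell and 0 rose (12 lower when adjusted over the list alone, median -1.23), with Bst1 at -2.14 and Lyve1 at -1.91. Camera placed these lists below other genes (adjusted p = 2.77e-06, 0.000467 and 0.000467), and each call was lost with an estimated correlation (adjusted p = 0.684 with an estimated correlation for all 3). Among aerocyte markers, which mark the capillary cells of gas exchange, 2 of 12 rose and 2 fell (2 and 2 when adjusted over the list alone, median 0.12; camera, adjusted p = 0.860). The members that rose were Emp2 (1.02) and Fibin (1.44) and those that fell were Nrp1 (-1.30) and Kdr (-1.21). Means of the aerocyte list relative to FL were -0.23, 0.74 and -0.41 in EC-KO 1, 2 and 3. Beside them, epithelial means were 1.82, 2.42 and 1.75 and pan-endothelial means -1.37, -0.52 and -1.39. The direction of the aerocyte list was downward without FL 1 (adjusted p = 0.855), without EC-KO 2 (0.183), without both (0.0789, chosen after seeing the data) and with fry (0.989). Without FL 2, FL 3, EC-KO 1 and EC-KO 3 the arterial falls numbered 9, 9, 8 and 9, and the venous falls numbered 5 without FL 3 and 4 without EC-KO 1. Emp2 was not called without FL 1, FL 2 or FL 3 (0.1002, 0.0917 and 0.0703), Fibin without FL 1, FL 2, EC-KO 1 or EC-KO 2 (0.104, 0.107, 0.0617 and 0.0797), Nrp1 without EC-KO 1 (0.0520), and Kdr without FL 3 or EC-KO 1 (0.0553 and 0.0589).

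Markers of other lung cells moved in both directions. Of 18 epithelial markers 17 rose and 0 fell (17 when adjusted over the list alone), with a median of 2.15. Sftpc, the surfactant protein of alveolar type II cells, went from 587 to 5521 CPM (3.23), and Epcam (2.20) and Cdh1 (2.43) rose as well. Of 19 fibroblast markers 12 rose and 0 fell (14 when adjusted over the list alone, median 1.39), with Dcn at 2.90 and Serpinf1 at 3.52. Of 10 mesothelial markers 4 rose and 0 fell (5 when adjusted over the list alone, median 0.75), namely Wt1, Krt19, Krt8 and Krt18, of which the keratins are also made by epithelium, and Wt1 (1.21) was not called without FL 2 (0.120), FL 3 (0.146) or EC-KO 3 (0.145). Erythroid and platelet markers rose in 8 of 11 cases, with 0 falling (10 when adjusted over the list alone, median 1.82), among them Itga2b (1.40). The median was also 1.82 with a bound, from a floor of 3 counts over the group, in place of any fitted value against a group at 0 counts. Camera gave adjusted p-values of 2.47e-11, 5.81e-07, 0.00729 and 4.73e-05 for these 4 lists, each lost with an estimated correlation (adjusted p = 0.322 with an estimated correlation for all 4). The epithelial rises numbered 10 without FL 3, and the erythroid and platelet rises numbered 3 without FL 2, 2 without FL 3, 5 without EC-KO 2 and 3 without EC-KO 3.

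Macrophage and monocyte markers fell in 17 of 20 cases and rose in 0 (18 lower when adjusted over the list alone), with a median of -2.07. Mrc1 (-2.91), Adgre1 (-2.30) and the Fc receptor Fcgr1 (-2.80) were among them. Of 11 neutrophil and mast cell markers 6 fell and 0 rose (6 lower and 1 higher when adjusted over the list alone, median -1.87), with Cxcr2 at -4.02 and Kit at -2.03. Lymphatic endothelial markers fell in 6 of 10 cases (6 when adjusted over the list alone, median -1.04), with Prox1 at -1.59. Smooth muscle and pericyte markers fell in 10 of 15 cases (11 when adjusted over the list alone, median -0.96), with Lmod1 at -1.58 and Cspg4 at -1.32. In these last 2 lists 0 members rose. Camera gave adjusted p-values of 1.07e-14, 0.00251, 0.00138 and 2.86e-05 for the 4 lists. These calls were lost with an estimated correlation (adjusted p = 0.241 with an estimated correlation for macrophages and 0.322 for the other 3). Lymphocyte markers were mixed, with 3 of 15 higher and 2 lower (3 and 2 when adjusted over the list alone, median 0.13; camera, adjusted p = 0.919). Means relative to FL were 0.47, -0.53 and 0.16 in EC-KO 1, 2 and 3, and camera called the list higher without FL 1 and EC-KO 2 (0.0451), a comparison chosen after seeing the data. The natural killer cell genes Nkg7 (1.03) and Klrb1c (1.18) rose and Il7r (-1.21) and Cd3g (-0.80) fell. Nkg7 was not called without FL 2, FL 3 or EC-KO 1 (0.0666, 0.0657 and 0.0605), Klrb1c without EC-KO 1 (0.0527), Il7r without FL 2 (0.0737), and Cd3g without FL 1, FL 2, FL 3 or EC-KO 3 (0.0804, 0.0910, 0.0853 and 0.0925). The falls of smooth muscle markers numbered 6 without FL 3 and 4 without EC-KO 1.

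Of 5 sex-linked genes measured, Uty was the 1 called (-0.63, adjusted p = 0.0412 in edgeR, 0 called when adjusted over the list alone; list median -0.07; camera, adjusted p = 0.528), and it was not called without FL 2, FL 3 or EC-KO 1 (0.151, 0.0953 and 0.130). Ddx3y, on the Y chromosome, was at 232 and 245 CPM in FL and EC-KO, and Xist at 0.752 and 0.854 CPM.

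**Figure D2:**
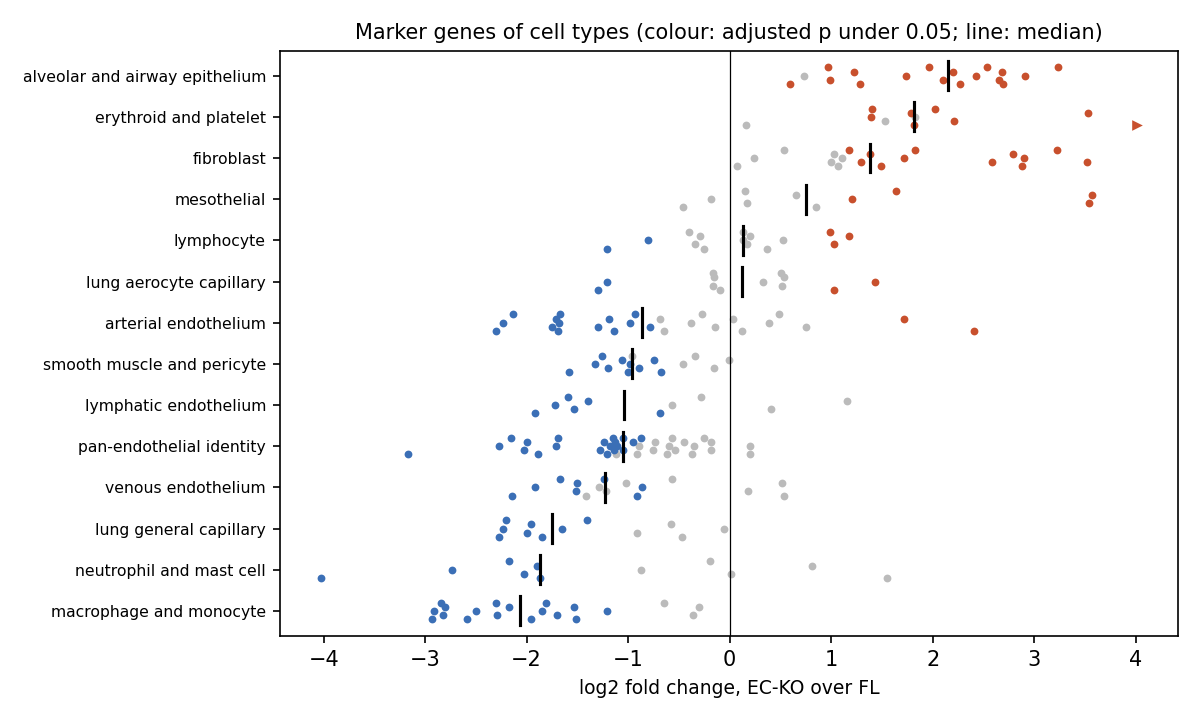
Log2 fold changes of EC-KO over FL (horizontal axis) for members of the marker and endothelial lists, with 1 point per gene (a triangle marks a lower bound), coloured where edgeR's adjusted p was under 0.05, and a line at each list's median. Epithelial (median 2.15) and fibroblast (1.39) markers lay mostly above 0, and macrophage markers (-2.07) below 0.

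Among genes of BMP signalling and of hereditary pulmonary arterial hypertension, falls outnumbered rises, beside lower endothelial markers (median -1.05). In that list 10 of 30 members fell and 1 rose (12 and 1 when adjusted over the list alone, median -0.49). Its members Eng, Sox17 and Kdr are also on the pan-endothelial list. Bmpr2, the receptor most often mutated in the heritable disease, went from 1253 ± 159 to 436 ± 181 CPM (log2 fold change -1.52 ± 0.28 SE, adjusted p = 0.00593 in edgeR). Acvrl1 (-1.57), Cav1 (-1.28) and Smad6 (-2.23) fell too, and Eif2ak4 rose (0.53). The list lay below other genes (camera, adjusted p = 0.0109, adjusted p = 0.684 with an estimated correlation). It had 16 falls in the comparison without FL 1 and EC-KO 2, chosen after seeing the data. The rise of Eif2ak4 was not called without FL 1, FL 2, FL 3, EC-KO 1 or EC-KO 3 (adjusted p = 0.125, 0.0865, 0.181, 0.101 and 0.158), nor the fall of Cav1 without FL 3, EC-KO 1 or EC-KO 3 (0.0722, 0.0754 and 0.0564).

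Secreted growth factors and vasoactive mediators fell more often than they rose: 15 of 36 were lower and 4 higher (16 and 7 when adjusted over the list alone, median -0.37). Edn1, the precursor of the vasoconstrictor endothelin 1, went from 294 ± 55.3 to 85.9 ± 25.7 CPM (-1.77 ± 0.24 SE, adjusted p = 0.00172 in edgeR). Cxcl12 (-2.24), which is also on the general capillary and arterial lists, and Pdgfc (-2.78) fell, and Fgf2 (1.22) and Tgfb1 (0.85) rose. Pdgfb (0.16, adjusted p = 0.649), Nos3 (0.20, adjusted p = 0.613) and Vegfa (-0.36, adjusted p = 0.276) did not pass the test. The values of Pdgfb and Nos3 were -0.20 and -0.21 without EC-KO 2. That library had the highest means of the 6 for aerocyte (0.74), epithelial (2.42) and fibroblast (2.30) markers. It also had the highest pan-endothelial mean of the EC-KO libraries (-0.52). Vegfa was at -0.57 without EC-KO 2 (adjusted p = 0.0558) and, chosen after seeing the data, was called lower without FL 1 and EC-KO 2 (-0.73, adjusted p = 0.00735). FL 1 and EC-KO 2 were the libraries nearest the other group in pan-endothelial markers. List means relative to FL were -0.65, -0.06 and -0.69 in EC-KO 1, 2 and 3. The list lay below other genes (camera, adjusted p = 0.0249, adjusted p = 0.684 with an estimated correlation), and not without EC-KO 1 (0.0656) or EC-KO 3 (0.0885). The rises numbered 0 without FL 2 and 0 without FL 3, Fgf2 was not called without FL 1, FL 2 or FL 3 (0.0590, 0.0516 and 0.0745) or Tgfb1 without FL 2 or FL 3 (0.0523 and 0.0559), and endothelial markers were lower in the same libraries (median -1.05).

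Among genes induced by hypoxia and genes of glycolysis, falls outnumbered rises, though most members were not called. In the hypoxia list 11 of 31 members fell and 1 rose (11 and 2 when adjusted over the list alone, median -0.26), including Ddit4 (-1.77) and Mxi1 (-1.26), while the collagen cross-linking enzyme Lox rose (1.74) beside fibroblast markers (median 1.39). In the glycolysis list 6 of 21 fell and 1 rose (8 and 2 when adjusted over the list alone, median -0.35). The lactate exporter Slc16a3 went from 292 ± 82.0 to 28.0 ± 1.64 CPM (-3.38 ± 0.24 SE, adjusted p = 0.000352 in edgeR), Eno1 fell by 1.29 on the log2 scale and Hk2 rose (1.41). Means of the hypoxia list relative to FL were -0.54, -0.06 and -0.70 in EC-KO 1, 2 and 3, beside endothelial marker means of -1.37, -0.52 and -1.39. Both lists lay below other genes (camera, adjusted p = 0.00589 each, adjusted p = 0.684 with an estimated correlation for both). Of the transcription factors and their regulator, Epas1 fell (-1.05 ± 0.30 SE, adjusted p = 0.0311), Hif1a did not pass (-0.39, adjusted p = 0.0923; 0.0438 with DESeq2) and Vhl rose (0.69, adjusted p = 0.0322). Epas1 is also on the pan-endothelial list, whose median was -1.05. Epas1 was not called without FL 2, FL 3, EC-KO 1 or EC-KO 3 (adjusted p = 0.0819, 0.106, 0.109 and 0.0952), nor Vhl without FL 1, FL 2, FL 3, EC-KO 1 or EC-KO 3 (0.0742, 0.117, 0.111, 0.122 and 0.0937). The glycolysis falls numbered 10 without EC-KO 2 and, chosen after seeing the data, 12 without FL 1 and EC-KO 2.

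Genes of fatty acid use fell in 8 of 29 cases and rose in 1 (8 and 1 when adjusted over the list alone, median -0.27). Slc27a4, a fatty acid transporter, fell by 2.21 on the log2 scale, the lipase Lpl by 1.85 and the receptor Pparg by 1.69, and Pdk4 rose (1.10). Lpl is also on the general capillary list, whose median was -1.75. Means of the fatty acid list relative to FL were -0.54, -0.18 and -0.58 in EC-KO 1, 2 and 3, beside pan-endothelial means of -1.37, -0.52 and -1.39. The fatty acid list lay below other genes (camera, adjusted p = 0.0109, adjusted p = 0.684 with an estimated correlation). There were 13 falls without EC-KO 2, and Pdk4 was not called without FL 2 (0.0502). Genes of cholesterol synthesis rose in 9 of 24 cases and fell in 3 (12 and 3 when adjusted over the list alone, median 0.47), including Sqle (0.96) and Cyp51 (0.93), while Dhcr7 (-1.05) and Stard4 (-0.49) fell. Epithelial markers rose in the same libraries (median 2.15). Camera placed the list above other genes (adjusted p = 0.0409, adjusted p = 0.684 with an estimated correlation), but not without FL 1 (0.0779), FL 3 (0.0791) or EC-KO 2 (0.119), nor without FL 1 and EC-KO 2 (0.154, chosen after seeing the data), and the rises numbered 4 without FL 3. Stard4 was not called without FL 1, FL 2, FL 3, EC-KO 1 or EC-KO 3 (0.0760, 0.0924, 0.147, 0.143 and 0.110).

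Targets of the integrated stress response, which adjusts amino acid supply and translation, rose more often than they fell. In this list 17 of 27 members rose and 1 fell (17 and 2 when adjusted over the list alone), with a median of 0.80. The transcription factor Atf4 (0.80), the pro-apoptotic factor Ddit3 (1.62), the glutathione-degrading enzyme Chac1 (1.88) and the arginine transporter Slc7a1 (1.61) rose, and Vldlr fell (-1.65). Slc7a1 went from 66.0 ± 9.46 to 200.8 ± 22.0 CPM (edgeR, adjusted p = 0.000661). Mean values of the list relative to FL were 0.68, 0.85 and 0.66 in EC-KO 1, 2 and 3, and those of the epithelial markers in the same libraries were 1.82, 2.42 and 1.75. The list lay above other genes (camera, adjusted p = 0.000467) and moved on balance upward (fry, adjusted p = 0.000878), while the camera call was lost with an estimated correlation (adjusted p = 0.271 with an estimated correlation). The rises numbered 11 without FL 2 and 10 without FL 3, and Atf4 was not called in either case (0.0709 and 0.0615).

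Chaperones of mitochondria and the endoplasmic reticulum went both ways, with 3 of 26 higher and 7 lower (4 and 7 when adjusted over the list alone, median -0.23; camera, adjusted p = 0.144). Hspe1 (-1.62) and Pdia4 (-1.05) fell, and Hspa9 (0.64) and Herpud1 (0.53) rose. In the antioxidant list 7 of 28 fell and 4 rose (7 and 4 when adjusted over the list alone, median -0.13; camera, adjusted p = 0.241), with Nqo1 at -2.66 and G6pdx at -1.19 against Gclc at 1.65. In the list of immediate early and heat shock genes 7 of 22 fell and 4 rose (7 and 4 when adjusted over the list alone, median -0.30; camera, adjusted p = 0.0674). The inducible chaperones Hspa1b (-2.79) and Hspa1a (-2.34) fell, and the transcription factors Fosl1 (2.71) and Nr4a2 (0.88) rose. Chaperone falls numbered 4 without FL 1, 3 without FL 2, 2 without FL 3, 3 without EC-KO 1 and 3 without EC-KO 3, antioxidant falls 3 and heat shock list falls 4 without each of FL 2, FL 3, EC-KO 1 and EC-KO 3, while antioxidant rises numbered 1 without each of FL 1, FL 2, FL 3 and EC-KO 1, and immediate early rises 2 without FL 3. Without EC-KO 2 camera called the chaperone (0.0310), antioxidant (0.0340) and immediate early and heat shock (0.0140) lists lower, and without FL 1 the last of these (0.0236). Without both, chosen after seeing the data, the 3 lists were called lower as well (0.0244, 0.0249 and 0.00435). Means relative to FL in EC-KO 1, 2 and 3 were -0.22, -0.06 and -0.39 for chaperones and -0.27, 0.18 and -0.36 for the antioxidant list. They were -0.39, -0.08 and -0.51 for immediate early and heat shock genes, beside pan-endothelial means of -1.37, -0.52 and -1.39. Hspa9 was not called without FL 2, FL 3 or EC-KO 1 (0.0694, 0.0910 and 0.0533), nor Herpud1 without FL 1, FL 2, FL 3, EC-KO 1 or EC-KO 3 (0.109, 0.103, 0.102, 0.0826 and 0.0786).

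Genes of mitophagy, the process in which Fundc1 acts, showed few calls. In the mitophagy and autophagy list 1 of 31 members rose and 1 fell (0 and 0 when adjusted over the list alone, median -0.16; camera, adjusted p = 0.235). The receptor Bnip3 fell (-0.99 ± 0.26 SE, adjusted p = 0.0223 in edgeR), its relative Bnip3l did not pass (-0.35, adjusted p = 0.219) and the adaptor Sqstm1 rose (0.71, adjusted p = 0.0212). Genes of mitochondrial fission, fusion and biogenesis rose in 3 of 21 cases and fell in 2 (3 and 1 when adjusted over the list alone, median 0.11; camera, adjusted p = 0.827), with Tfb2m at 1.11, Ppargc1a at 1.77, the fusion protein Opa1 at -0.76 and Ppargc1b at -1.35. Of the genes for ER-mitochondria contact and calcium transfer 6 of 25 fell and 1 rose (6 and 1 when adjusted over the list alone, median -0.12; camera, adjusted p = 0.144), with the calcium channel Itpr2 at -0.80 and the chaperone Hspa9 at 0.64. The ER-mitochondria falls numbered 2 without FL 2, 2 without FL 3, 3 without EC-KO 1, 10 without EC-KO 2 (camera, adjusted p = 0.0483) and 2 without EC-KO 3. Hspa9 was not called without FL 2, FL 3 or EC-KO 1 (0.0694, 0.0910 and 0.0533). Bnip3 was not called without FL 3, EC-KO 1 or EC-KO 3 (0.0877, 0.0854 and 0.0692), Sqstm1 without FL 1, FL 2 or FL 3 (0.0690, 0.0927 and 0.0827), Ppargc1a without FL 3 or EC-KO 3 (0.0729 and 0.0611), and Ppargc1b without FL 1, FL 2, EC-KO 1, EC-KO 2 or EC-KO 3 (0.138, 0.106, 0.0837, 0.0766 and 0.0873). With all 6 libraries, Ppargc1b also lost its call with upper-quartile factors (0.0588), library size alone (0.0648), limma-voom (0.0656) and the replicate block (0.0681).

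Nuclear genes of the respiratory chain had 1 of 76 members higher and 2 lower (0 and 0 when adjusted over the list alone, median 0.08; camera, adjusted p = 0.539). Uqcrh rose (0.63) and Sdha (-0.66) and Atp5c1 (-0.51) fell. Uqcrh was not called without FL 2, FL 3 or EC-KO 1 (0.0854, 0.0729 and 0.0652), Sdha without FL 3, EC-KO 1 or EC-KO 3 (0.0632, 0.0584 and 0.0597), and Atp5c1 without FL 2, FL 3, EC-KO 1 or EC-KO 3 (0.113, 0.135, 0.0969 and 0.129). Of the 13 mitochondrially encoded proteins 0 were called (0 when adjusted over the list alone, median 0.52), and the most abundant, mt-Co1, was at 16051 ± 2511 and 18615 ± 4158 CPM (0.21, adjusted p = 0.535). Camera placed this list above other genes (adjusted p = 0.0289, adjusted p = 0.684 with an estimated correlation), and not without FL 2 (0.0668), FL 3 (0.0791), EC-KO 1 (0.0825) or EC-KO 2 (0.103). Mitochondrial genes took 3.42%, 2.55% and 2.49% of counts in FL 1, 2 and 3 and 4.36%, 4.27% and 3.07% in EC-KO 1, 2 and 3.

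Inflammatory genes of the NF-kB and leukocyte adhesion list rose in 12 of 31 cases and fell in 3 (12 and 8 when adjusted over the list alone, median 0.52; camera, adjusted p = 0.144). The chemokine Cxcl5 (3.50) and the macrophage growth factor Csf1 (2.06) rose, and Il1b (-2.30) and Tnfaip2 (-1.49) fell beside macrophage markers (median -2.07). The list's means relative to FL were 0.36, 0.78 and 0.22 in EC-KO 1, 2 and 3, beside 1.59, 2.30 and 0.79 for fibroblast markers and 1.82, 2.42 and 1.75 for epithelial markers. Il1b went from 2515 ± 203 to 511 ± 28.0 CPM (edgeR, adjusted p = 0.000352). Interferon-stimulated genes rose in 4 of 40 cases and fell in 2 (1 and 2 when adjusted over the list alone, median 0.34; camera, adjusted p = 0.193), with Irf9 at 0.96 and Ifit3 at 1.03 against Oas3 at -1.52 and Ifnb1 at -1.73. The NF-kB rises numbered 6 without FL 2 and 6 without FL 3, and camera called that list higher without FL 1 (0.0365) or EC-KO 3 (0.0478). Interferon rises numbered 8 without FL 1 and 1 without FL 2, FL 3, EC-KO 2 or EC-KO 3, camera called that list higher without FL 1 (0.00806) or EC-KO 1 (0.0293), and Ifit3 was not called without FL 2, FL 3, EC-KO 2 or EC-KO 3 (0.138, 0.155, 0.105 and 0.0733).

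Genes of the mesenchymal transition of endothelium and of matrix went both ways, with 8 of 31 higher and 6 lower (8 and 6 when adjusted over the list alone). Their median was -0.15, their mean 0.03 and the direction of camera downward (adjusted p = 0.634), so these differed in sign. The protease Mmp2 (1.62) and the inhibitor Timp1 (2.89) rose beside fibroblast markers (median 1.39), Timp1 without a call when low counts were not filtered (0.0693), and Tgfbi (-2.07) and Notch3 (-1.26) fell beside macrophage (-2.07) and smooth muscle (-0.96) markers. The rises numbered 5 without FL 1, 5 without FL 2 and 5 without FL 3, and the falls numbered 13 without EC-KO 2.

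Genes of proliferation fell in 6 of 36 cases and rose in 2 (4 and 1 when adjusted over the list alone, median -0.28; camera, adjusted p = 0.261), with Ccna2 at -1.21 and Cenpf at -1.74 against the replication licensing factors Cdt1 (1.47) and Cdc6 (0.91). Targets of p53 and senescence genes fell in 7 of 24 cases and rose in 4 (7 and 5 when adjusted over the list alone, median -0.33; camera, adjusted p = 0.132), with Eda2r at -1.51 and Glb1 at -1.06 against Mdm2 at 0.67. Proliferation falls numbered 2 without FL 2, 3 without FL 3, 2 without EC-KO 1 and 3 without EC-KO 3, and p53 falls 11 without EC-KO 2. The p53 rises numbered 2 without FL 1, 0 without FL 2, 0 without FL 3 and 1 without EC-KO 1, and without FL 1 camera called that list lower (0.0473), as it did without FL 1 and EC-KO 2 (0.0244, chosen after seeing the data). Cdt1 was not called without FL 2, FL 3 or EC-KO 1 (0.0566, 0.0616 and 0.0553), Cdc6 in any fit that left out 1 library (0.0559 to 0.170), and Mdm2 without FL 2 or FL 3 (0.0560 and 0.0853).

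**Figure D3:**
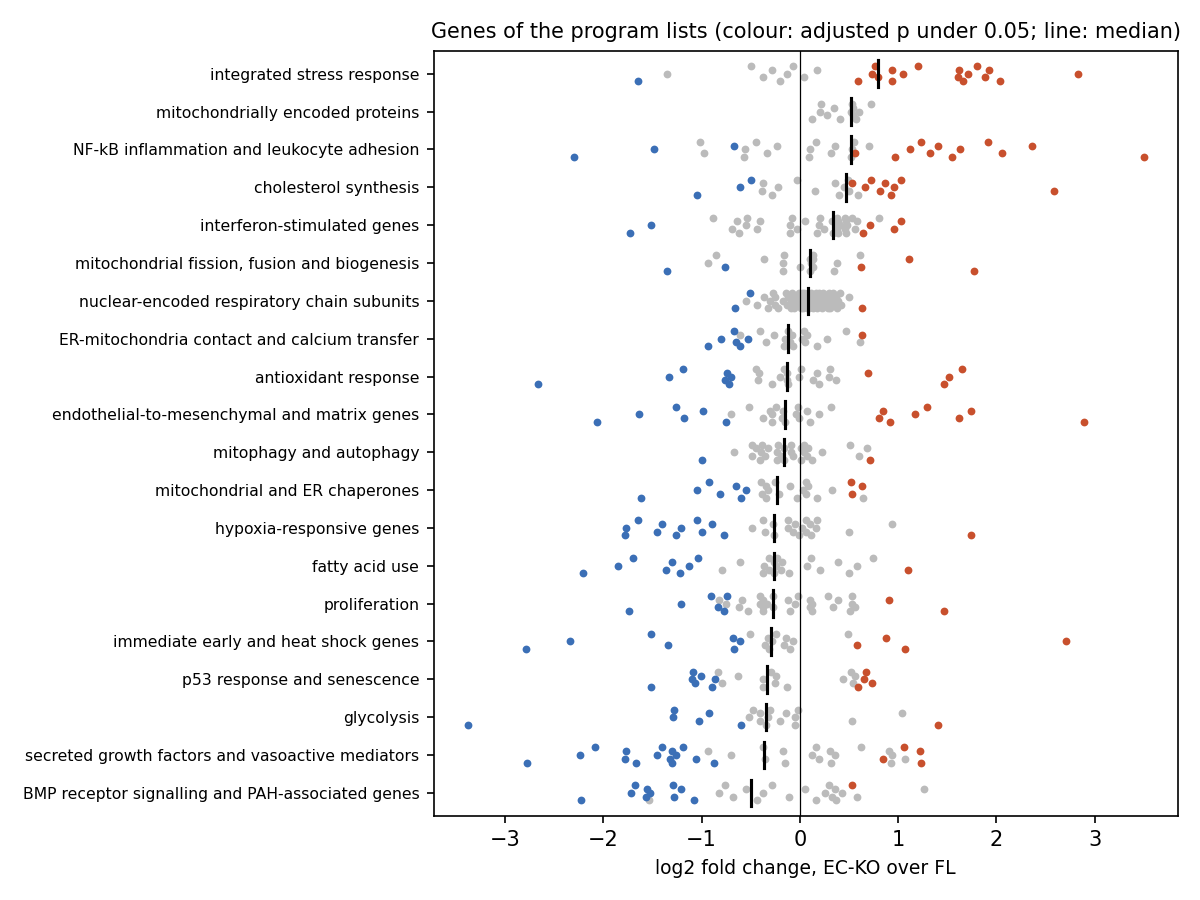
Log2 fold changes of EC-KO over FL (horizontal axis) for members of the other program lists, with 1 point per gene, coloured where edgeR's adjusted p was under 0.05, and a line at each list's median. Most members of the integrated stress response (median 0.80) lay above 0 and most of the BMP and pulmonary arterial hypertension list (-0.49) below 0.

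Of the 25 program lists, 12 passed camera (3 higher, 9 lower), 0 passed with an estimated correlation (lowest adjusted p = 0.271 with an estimated correlation) and 2 passed fry, the integrated stress response (0.000878) and glycolysis (0.0136). Of the 10 marker lists, 8 passed camera, 0 passed with an estimated correlation (lowest adjusted p = 0.241 with an estimated correlation) and 8 passed fry.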

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

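The comparison of 2 against 2 libraries, without FL 1 and EC-KO 2, and the scaling to the pan-endothelial list were chosen after the results were seen, and the other alternatives before the data were examined. The count of 5029 changed genes moved with the libraries and with stricter thresholds. Leaving out 1 library gave 2547 (without FL 3) to 6740 (without EC-KO 2) changed genes, with 1169 to 3009 higher and 1314 to 3731 lower. The 2 against 2 comparison gave 7554 (4074 lower). RLE, upper-quartile and library-size scaling and changes of filter and robust fitting gave 4841 to 5261, limma-voom 5129 and DESeq2 6191. An adjusted p under 0.01 gave 2015 (977 higher, 1038 lower), a fold of at least 2 gave 3100 (1359 lower), and a test against a change of 1.5 times gave 1899 (1017 higher, 882 lower), all fewer by construction. The share of higher calls was 57.4% with upper-quartile factors and 57.5% with library size alone, where TMM gave 2515 of 5029. Of the 25 program lists, 12 passed camera, 0 with an estimated correlation, 2 with fry and 10 to 15 when 1 library was left out.

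Fundc1 was lower in every alternative on all genes, at -1.15 to -0.87 with 1 library left out, and at 0.12 when scaled to the pan-endothelial list. That scaling moved the median gene by 1.12 and gave 10686 changed genes (10421 higher, 265 lower). A gene whose fall was close to the median of the list (-1.05), such as Fundc1 (-0.96), comes out near 0 under it. The scaling was narrowed to Fundc1, the endothelial lists and 3 targets of the aryl hydrocarbon receptor after its effect on other genes was seen. Pdgfb ranged from -0.20 (without EC-KO 2) to 0.31 and Nos3 from -0.21 (without EC-KO 2) to 0.41 when 1 library was left out, and they were at -0.26 and -0.28 in the 2 against 2 comparison. Some lists that had not passed camera changed direction for at least 1 library left out, with adjusted p-values over all 6 of 0.491 to 0.985 for mitochondrial fission, fusion and biogenesis, 0.0895 to 0.886 for the nuclear respiratory chain, 0.183 to 0.878 for aerocytes, 0.144 to 0.886 for mesenchymal and matrix genes and 0.194 to 0.915 for lymphocytes. In the 2 against 2 comparison this held for the respiratory chain (0.755) and aerocytes (0.0789), and with fry for aerocytes (0.989). The cause was not tested.

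With the replicate number as a block, 3848 genes were changed (1900 higher, 1948 lower), 74.5% of the calls were shared, Fundc1 was at -0.97 (adjusted p = 0.0151), 11 program lists passed, and cholesterol synthesis did not (0.0533). The pairing was not borne out, since deviations from the group mean correlated at 0.05, 0.07 and -0.18 across genes, which are not independent replicates, for libraries of the same number. Of 154 genes followed through the alternatives 142 kept their result with the block and 12 lost the call. Leaving out 1 library ended the call of 4 (EC-KO 2) to 32 (FL 3) of them. Without FL 1, 12 calls ended. No low-count filter ended 7, upper-quartile factors 5, library size alone 5, limma-voom 1 and DESeq2 0. The calls that ended with upper-quartile factors and with library size alone were those of Ppargc1b, Atp5c1, Stard4, Cd3g and Uty. At 26.7 M to 34.3 M counts per library 18562 genes had enough counts to be tested, and whether depth limits their calls was not tested.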

Other observations

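All tests below were chosen after the results were seen, except the co-variation of marker lists and the splits of the libraries. Genes of the keratin-rich transitional state of alveolar epithelium, which appears during repair, rose in 12 of 19 cases and fell in 0 (13 when adjusted over the list alone), with a median of 2.18. The keratins Krt8 (3.54) and Krt18 (3.57) were among them. Genes of adventitial fibroblasts, which surround large vessels and airways, rose in 12 of 19 cases and fell in 0 (14 when adjusted over the list alone), with a median of 2.23, including the chemokine Ccl11 (4.06), Entpd2 (3.48) and the actin-severing protein Gsn (2.23). Both lists were written after the data were seen and hold genes that prompted them, so no test of them is given. General epithelial markers rose as much (median 2.15), with means relative to FL of 1.82, 2.42 and 1.75 in EC-KO 1, 2 and 3 against 1.86, 2.45 and 1.94 for the transitional list.

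Cytosolic heat shock genes, whose products refold proteins, fell in 10 of 17 cases and rose in 1 (11 and 1 when adjusted over the list alone), with a median of -0.58, in a list also written after the data were seen. Its means relative to FL were -0.83, -0.52 and -0.93 in EC-KO 1, 2 and 3, beside pan-endothelial means of -1.37, -0.52 and -1.39. Hspa1b (-2.79), Hsph1 (-1.51) and Dnajb1 (-1.35) fell, while the small heat shock protein Cryab rose (1.34), though not without FL 2 (adjusted p = 0.0508). Immediate early genes, which respond within minutes to stimulation, rose in 4 of 16 cases and fell in 3 (4 and 3 when adjusted over the list alone), with Fosl1 at 2.71 and Fosb at 1.07 against Fos at -0.68. Their median was -0.20 and their mean 0.08, so these differed in sign. Fosb was not called without FL 3 (0.0553), nor Fos without FL 2 (0.139), FL 3 (0.123), EC-KO 1 (0.124) or EC-KO 3 (0.126).

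Endothelial and macrophage markers were lower and epithelial and fibroblast markers higher in EC-KO. The cells were isolated with magnetic beads, whose antibody is not named, and cleared of dead cells. How far these steps lowered other cell types was not measured, and they need not remove them. Levels of abundant markers in FL and EC-KO were 1752 and 4266 CPM for Scgb1a1, 587 and 5521 CPM for Sftpc, 178 and 632 CPM for Inmt, and 3494 and 486 CPM for Chil3. A lower endothelial share alone would raise other types alike, yet the epithelial and macrophage medians differed by 4.22, and 8 pan-endothelial members still differed after scaling to that list's own median (Clec14a -2.13, Nos3 1.20), some of which other cells make too. Members of the epithelial, fibroblast and macrophage lists deviated together within groups (mean r between members 0.546, 0.845 and 0.266 over the 6 libraries, lowest percentile 99.8 among 10000 random lists of genes with similar levels). A mix of cell types that varied between isolates is a candidate explanation. Random genes share no cell type, so any influence shared by the markers of a cell type would give this too. The comparison therefore does not single out a varying mix. Effects of the knockout on these cells or on their recovery stay open and untested, and 3 fibroblast genes are also on the mesenchymal and matrix list.

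Cyp1a1, Cyp1b1 and Ahrr fell by more than the median of any cell type list. All 3 were still lower when scaled to the pan-endothelial list (edgeR, highest adjusted p = 0.000214) and when scaled to the macrophage list (0.000325). They had been picked as the largest falls, so this outcome was near certain from the list medians (-1.05 and -2.07). It shows only that they fell by more than the typical marker of either list. A list median does not bound the loss of a scarcer kind of cell, so a change in cell types stays open. Lower activity of the aryl hydrocarbon receptor may be behind the falls, but the other targets had a median of -0.33, with 3 of 10 lower and 1 higher (3 and 2 when adjusted over the list alone, camera adjusted p = 0.285, fry downward with adjusted p = 0.0318). Of these targets 7 lay below 0 and 3 above, from -2.66 (Nqo1) to 1.22. Cyp1a2, too low to test, had 2, 4 and 5 counts in FL 1, 2 and 3 and 0 in each EC-KO library. Members went both ways, so the list does not decide the question. Ahr itself was at -0.43 (adjusted p = 0.150). An effect of the knockout stays open and untested.

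Fundc1 was 1.94-fold lower on the scale of all genes. Scaled to the pan-endothelial list its change was 0.12 ± 0.31 (adjusted p = 0.736, with 0.000124 to 0.736 over all alternatives), but that scaling moved the median gene by 1.12, so the value does not decide between loss of the transcript and a lower endothelial share. A lower endothelial share would account for a fall of this size only if the other cells made little Fundc1. Fundc1 was not measured in single cell types, so this is not known. The gene count covers undeleted exons and may include reads of other cells in the isolates. Both explanations stay open.

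With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split gave 5029 changed genes and the highest other 0, so 1 split of 10 reached the real count. For program lists past camera the real split gave 12 and the highest other 15, so 4 of 10 reached the real count.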
